A study of Prunus persica with 16 samples.

How the data were processed

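Buds of the peach cultivar TropicBeauty were profiled by mRNA sequencing in 16 libraries, 4 from trees sprayed with hydrogen cyanamide (HC) and 4 from untreated trees at each of 2 times, 3 and 7 days after treatment. Per the labels, each of the 4 replicates of a treatment was a separate tree, and libraries followed the Illumina TruSeq mRNA protocol from total RNA. The labels mention surfactant for the HC spray alone, so HC and surfactant were not separated by the design. The labels give 4 trees per treatment, so by that number buds of both times came from the same trees. They do not say whether 1 replicate number was 1 tree at both times. The main fits treat the 16 libraries as independent. Groups and replicate numbers were taken from the labels.

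Trimmomatic, STAR 2.5.2a and RSEM 1.2.31 are listed, without role or order, per the submitters' processing notes. The genome build was not given in the sources used here. The deposited expression matrix held 26873 gene identifiers and 1 column per library. Its values were FPKM as far as the numbers show. Of the values above 0, between 98.9% and 99.2% per library were not whole, and each library's FPKM summed to between 1052238 and 1209106 while the number of genes above 0 ranged from 8667 to 18378. The authors also deposited 1 table per day with a log2 fold change of HC over control, an adjusted p-value and 1 signal value per gene and treatment. The method behind the deposited p-values and the deposited log2 fold changes was not given in the sources used here. By their numbers, the deposited signal values were close to weighted sums of FPKM over the 4 libraries of a treatment, times a factor per gene that acted like gene length.

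The test fixed before the data were examined was a count test on estimated counts. The matrix held FPKM, so limma 3.58.1 in R 4.3.3 was used in its place, on log2(FPKM + 1), with 1 mean per group over all 16 libraries and empirical Bayes moderation with trend and robust settings (statmod 1.5.0). Genes with an FPKM of 1 or more in at least 4 libraries were tested, which left 16596 genes. The pseudocount of 1, this filter and the limma settings were chosen after the unit was known. The comparisons, the threshold (Benjamini-Hochberg adjusted p under 0.05) and the use of all libraries were fixed before. The contrasts were HC against control at 3 days, the same at 7 days, the difference between these effects, and 7 against 3 days within each treatment. A fold change is on the log2(FPKM + 1) scale, which understates changes of low genes, and errors of log2 fold changes are standard errors from limma. An FPKM of 0 states only that the gene was listed at 0 in that library.

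Sequencing depth was estimated, since FPKM carries none directly. For 18510 genes in both deposited tables, the ratio of the deposited signal to FPKM gave a length-like factor per gene, which had a quartile range of 0.0123 (log2) between the tables of the 2 days. After multiplying by it, low values of a library fell on multiples of a step, taken as 1 read. The share of low values within 0.2 of a whole number of steps was between 78.0% and 87.2% in 13 libraries, against 40% by chance. It was 69.0% in HC replicate 3, 56.0% in HC replicate 1 and 43.5% in control replicate 4 at 3 days, so the depth of these 3 libraries is less certain. The estimated reads were used for depth, for 1 alternative test and for thinning, and not for the main counts of genes.

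The matrix gave no gene name for any identifier, and 0 of the 26873 identifiers matched the 26412 genes of the reference table. Of 32 gene lists fixed before the data were examined, 31 were defined by product names and were not tested here. The DAM list (dormancy-associated MADS-box genes) was fixed by 6 identifiers taken from general knowledge of the peach annotation, not from the files. Of these, 4 passed the filter, under the minimum of 5 for a gene set test, so members were tested one by one, over all genes and adjusted over the list alone. DAM genes are close copies of each other, and reads shared between copies make the level of each member uncertain.

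Other genes are named by identifier under a rule fixed before the data were examined for files without gene names. It takes, per contrast, the 2 highest and 2 lowest log2 fold changes among genes with adjusted p under 0.05, no overlap between the 4 libraries of each group and a mean FPKM of 1 or more. FPKM stood in for CPM in the rule. For the difference between effects, which involves 4 groups, only the mean was required, a choice made when the rule was applied. All DAM list members that passed the filter are given too.

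The fit was tested on simulated reads for the real genes and depths, with 50 genes changed per fold size. At 3 days (16572 genes), 6% of 2-fold, 42% of 4-fold, 64% of 8-fold and 62% of 16-fold changes were called, and 9 of 96 calls were false (9.38%). At 7 days (16625 genes), the shares were 14%, 38%, 56% and 72%, and 3 of 93 calls were false (3.23%). Each figure is from 1 simulated data set. The simulation gave each gene 1 mean and 1 spread, apart from the changed genes. Differences between libraries other than depth were not simulated, so these shares may not hold for the real data. Overlaps of gene sets used Fisher's exact test, two-sided. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.

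Alternatives fixed before the data were examined were another scaling (median of ratios), limma voom with sample quality weights, no filter on low values, only the libraries of the groups compared, stricter thresholds, a replicate block, and leaving out each library in turn. The block was replicate number within day for HC against control, and treatment with replicate number, as if 1 number were 1 tree at both days, for the difference and for time. Voom was run on the estimated reads. Pseudocounts of 0.1 and 5, a floor of 5 FPKM, sample quality weights on log2 FPKM and the fit without the 2 shallowest libraries were chosen after seeing the data.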

Results

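Hydrogen cyanamide is a growth regulator sprayed on dormant fruit trees to bring forward bud break. The study asked which transcripts differed between buds of HC-treated and untreated peach trees before bud break. The 5-year-old TropicBeauty trees, grafted on Floridaguard rootstock, had met 11 of their 150 chilling hours when 4 trees were sprayed with 1% (v/v) HC plus 0.15% (v/v) surfactant. Another 4 trees were left untreated. Buds were taken 3 and 7 days later, which gave 4 groups of 4 libraries.

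Depth differed widely between libraries. Estimated reads in genes ranged from 0.556 M (M, 1e6) in control replicate 1 at 7 days to 22.3 M in HC replicate 3 at 3 days, with a median of 4.77 M. The group medians were 7.29 M (control) and 10.8 M (HC) at 3 days, and 2.83 M (control) and 3.47 M (HC) at 7 days. Genes with an FPKM above 0 numbered from 8667 in control replicate 2 at 3 days to 18378 in HC replicate 1 at 7 days, and 5915 genes were above 0 in all 16 libraries. The median SD of a gene on the log2 scale was 1.04 and 0.61 (control and HC, 3 days) and 0.91 and 0.70 (control and HC, 7 days). Much of the control spread came from 1 library at each day: without control replicate 2 the SD at 3 days was 0.54, and without control replicate 1 the SD at 7 days was 0.66. The HC values fell too, to 0.48 without HC replicate 2 at 3 days and 0.53 without HC replicate 3 at 7 days. On these terms control stayed higher at both days.

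**Figure D1:**
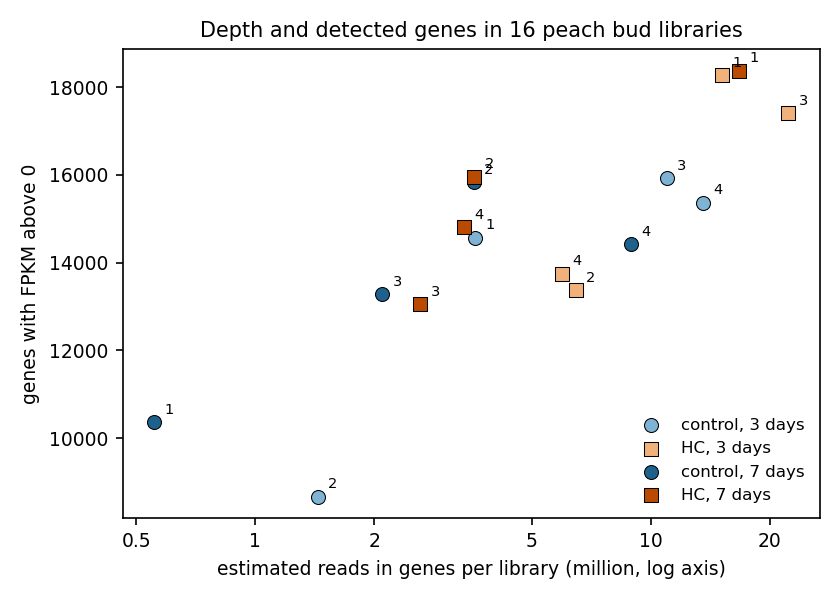
Estimated reads in genes (M, log axis) and the number of genes with an FPKM above 0 in each of the 16 libraries, 1 point per library, with the replicate number beside it. Control replicate 2 at 3 days (8667 genes) and control replicate 1 at 7 days (10356 genes) lie below the other 14 libraries, which range from 13052 to 18378 genes.

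At 3 days, 301 genes differed between HC and control buds, 179 higher and 122 lower in HC, out of 16596 tested. The largest increases that met the naming rule were in Prupe.4G155200 and Prupe.I000300. Prupe.4G155200 was listed at 0 in 3 control libraries and at 1.03 FPKM in control replicate 2, against 189 to 652 FPKM in the HC libraries (log2 fold change 8.07 ± 0.87, SE, adjusted p = 6.9e-05). Prupe.I000300 had 0, 0, 13.7 and 19.0 FPKM in control and 406 to 1312 FPKM in HC libraries (7.50 ± 1.14, adjusted p = 0.0019). Prupe.1G251600 had the lowest fold change by the rule, with 45.2 to 178 FPKM in control libraries and 0, 0.76, 6.52 and 6.53 FPKM in HC libraries (-5.03 ± 0.74, adjusted p = 0.00098). Prupe.1G327500 followed, with 47.1 to 281 FPKM in control libraries and 0, 3.50, 12.5 and 16.6 FPKM in HC libraries (-4.83 ± 0.84, adjusted p = 0.0052). The 301 changed genes had a median FPKM of 113, against 10.8 over all tested genes. Without HC replicate 1 the count was 169 and without HC replicate 4 it was 191, and it was 852 and 869 in the alternatives that weighted libraries by quality. Under voom on the estimated reads, which is the first of these, Prupe.4G155200 (adjusted p = 0.087, range over 20 alternatives 5.2e-07 to 0.087) and Prupe.1G327500 (adjusted p = 0.096, range 0.0017 to 0.096) were no longer called. Prupe.I000300 was absent from the authors' deposited tables of both days, so it had no estimated reads and was not in that fit. It was called in the other 19 alternatives.

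Of the 6 identifiers of the DAM list, MADS-box transcription factors of the locus tied to bud dormancy in peach, 4 were measured and Prupe.1G531200 and Prupe.1G531300 were listed at 0 in all 16 libraries. At 3 days, 3 of the 4 fell in HC buds, over all genes and adjusted over the list alone. Prupe.1G531100 had a mean of 92.5 ± 11.9 FPKM in control and 28.2 ± 13.1 FPKM in HC buds (SD, n = 4; log2 fold change -1.78 ± 0.37, SE, adjusted p = 0.0124). Prupe.1G531400 had 532 ± 183 FPKM in control and 191 ± 46.7 FPKM in HC buds (-1.45 ± 0.27, adjusted p = 0.0059). Prupe.1G531700 had 1042 ± 94.1 FPKM in control and 636 ± 94.0 FPKM in HC buds (-0.72 ± 0.15, adjusted p = 0.0133). In these 3 genes every HC library lay below every control library of that day, a separation (either way) that chance gives for a share of 0.0286 of genes. Prupe.1G531600 varied more between replicates, with 467 ± 285 FPKM in control and 305 ± 125 FPKM in HC buds (-0.31 ± 0.68, adjusted p = 0.91). Its log2 fold change was 0.06 without control replicate 1 and 0.005 without HC replicate 1, and it was called under voom on the estimated reads (-1.10, adjusted p = 0.021, range over 20 alternatives 0.021 to 1.00). The call of Prupe.1G531100 was lost without HC replicate 1 (adjusted p = 0.058, range over 20 alternatives 0.0012 to 0.058). That of Prupe.1G531700 was lost without control replicate 1, control replicate 3 or HC replicate 1 (adjusted p from 0.0502 to 0.062, range over 20 alternatives 8.1e-06 to 0.070), and with replicate number as a block (adjusted p = 0.070).

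At 7 days, Prupe.1G531700 was lower in HC buds at 699 ± 72.9 FPKM, against 1316 ± 212 FPKM in control (SD, n = 4; -0.90 ± 0.15, SE, adjusted p = 0.0154), again with no overlap between the libraries. The other 3 members had negative fold changes that did not pass the test over all genes. Prupe.1G531400 had 675 ± 213 FPKM in control and 324 ± 55.3 FPKM in HC buds (-1.01 ± 0.27, adjusted p = 0.10). Prupe.1G531100 had 206 ± 86.6 and 109 ± 21.1 FPKM (-0.82 ± 0.37, adjusted p = 0.42), and Prupe.1G531600 had 299.7 ± 143 and 108 ± 104 FPKM (-1.76 ± 0.68, adjusted p = 0.34). Adjusted over the list alone, all 4 members passed at 7 days, with the highest adjusted p at 0.038. The HC effect did not differ detectably between the days for any of the 4 (adjusted p from 0.59 to 0.83). Prupe.1G531700 was no longer called at 7 days when only the 8 libraries of that day were fitted (adjusted p = 0.071, range over 20 alternatives 7.1e-05 to 0.071) or with replicate number as a block (adjusted p = 0.070).

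**Figure D2:**
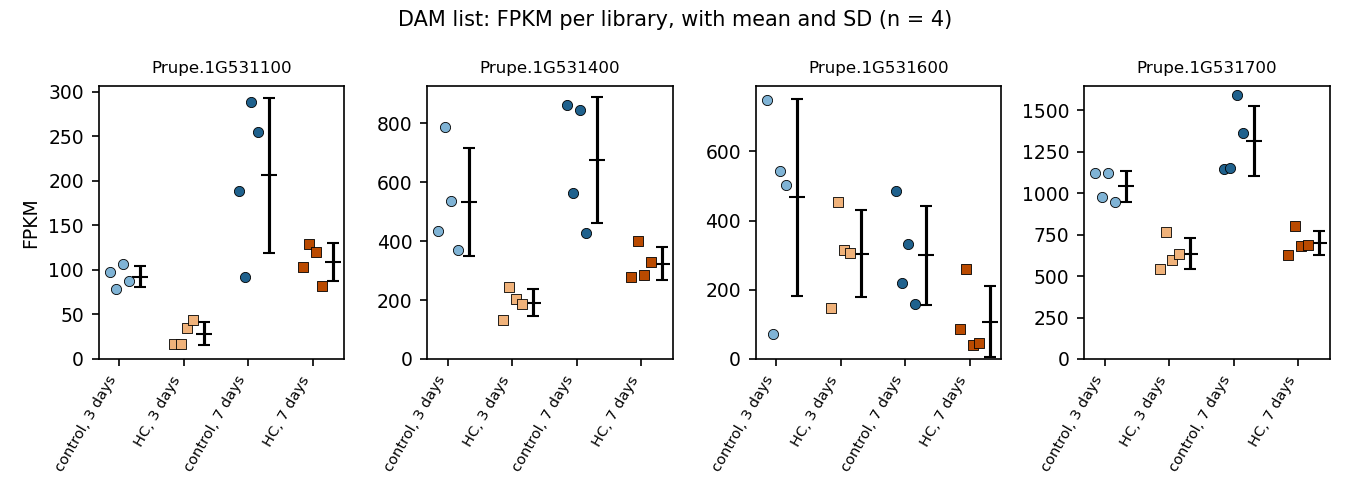
FPKM of the 4 measured DAM list members in each library (points, 4 per group) with the group mean and SD beside them, each panel on its own axis from 0. For Prupe.1G531700 the HC libraries lie between 543 and 799.95 FPKM at both days, and the control libraries between 946 and 1595 FPKM.

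Across all genes at 7 days, 74 differed between HC and control buds, 54 higher and 20 lower in HC, a split that depended on the processing (56 and 51 under voom on the estimated reads, 6 and 6 with replicate number as a block). Prupe.2G242800 was listed at 0 in 3 control libraries and at 1.57 FPKM in control replicate 4, against 51.7 to 374 FPKM in HC libraries (log2 fold change 6.51 ± 1.31, SE, adjusted p = 0.029). Prupe.3G144100 had 0, 0, 5.82 and 7.05 FPKM in control and 95.1 to 717 FPKM in HC libraries (6.32 ± 1.15, adjusted p = 0.024). Its deposited HC signal at 7 days was 627.54 for a mean of 294.73 FPKM. That of Prupe.2G242800 was only 31.851 for a mean of 153.58 FPKM. The length-like factor of Prupe.2G242800 was therefore small, and its high FPKM may stand for few reads. Prupe.2G181500 fell from 348 ± 132 FPKM in control to 42.5 ± 27.1 FPKM in HC buds (SD, n = 4; -3.13 ± 0.43, SE, adjusted p = 0.0034) and was called in all 20 alternatives. Prupe.2G240300 had 9.99 to 16.3 FPKM in control libraries and 0, 0, 2.52 and 3.50 FPKM in HC libraries (-2.89 ± 0.62, adjusted p = 0.042). The count of 74 depended on single libraries: it was 26, 30 and 31 without control replicate 1, 3 or 4, 166 without control replicate 2, 45, 40 and 30 without HC replicate 1, 3 or 4, and 14 when only the 8 libraries of that day were fitted. The calls of the 2 named increases and of Prupe.2G240300 were each lost in 9 to 15 of 20 alternatives, among them the fits without control replicate 1, control replicate 3, HC replicate 1 or HC replicate 3 and with replicate number as a block (adjusted p of 0.058, 0.074 and 0.097 with the block, range over 20 alternatives 0.0035 to 0.0998 for Prupe.2G242800, 0.0068 to 0.48 for Prupe.3G144100 and 0.033 to 0.20 for Prupe.2G240300).

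The HC effect itself differed between the days for 81 genes, 59 with a higher and 22 with a lower log2 fold change at 7 than at 3 days. Prupe.6G021700 was lower in HC buds at 3 days (log2 fold change -4.41) and higher at 7 days (3.34), a difference of 7.75 ± 1.10 (SE, adjusted p = 0.0042) that was called in all 27 alternatives. Its FPKM was 212 to 439.9 in control and 6.21 to 25.4 in HC libraries at 3 days, and 5.94 to 254 and 462 to 838 at 7 days. Prupe.6G021100 followed the same course, with -4.72 and 4.32 (difference 9.03 ± 1.82, adjusted p = 0.041), but its call was lost in 15 of 27 alternatives (range of adjusted p 0.0019 to 0.19), among them the fits without any 1 library other than HC replicate 2 of 3 days and control replicates 1 and 2 of 7 days (0.061 to 0.11). Its HC libraries had 0, 4.05, 6.47 and 25.3 FPKM at 3 days and 388 to 653 FPKM at 7 days, and its control libraries 117 to 279 FPKM and then 0, 25.4, 43.5 and 306 FPKM. Prupe.8G110900 was higher in HC buds by 6.91 at 3 days and 1.36 at 7 days (difference -5.55 ± 1.046, adjusted p = 0.025, lost in 12 of 27 alternatives, range 0.0012 to 0.14, and 0.091 with treatment and replicate number as a block). Prupe.8G000400 had 3.50 at 3 days and -1.87 at 7 days (difference -5.38 ± 1.07, adjusted p = 0.028, lost in 16 of 27, range 0.00013 to 0.13). Both were lost, among other fits, without replicate 4 of any group, HC replicate 3 of either day or control replicate 3 of 7 days (adjusted p from 0.052 to 0.073). With median-of-ratios scaling, 77 genes differed and the split changed to 45 higher and 32 lower, as the median over all genes moved from 0.10 to -0.02. The count was 204 under voom on the estimated reads, 227 with quality weights on log2 FPKM and 38 with treatment and replicate number as a block. Leaving out 1 library gave between 34 and 107 genes, and 49, 45 and 43 without HC replicate 1, 3 or 4 of 3 days, 46 and 37 without control replicate 3 or 4 of 3 days, 47, 42 and 34 without HC replicate 1, 3 or 4 of 7 days, and 53 and 46 without control replicate 3 or 4 of 7 days.

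Genes changed in both HC-control comparisons numbered 16. Of these, 5 were higher at both days (0.58 expected for independent lists; Fisher's exact test, two-sided, p = 0.00028), 7 were lower at both days (0.15 expected; p = 7.0e-11), and 4 changed in opposite directions. The comparisons share no library. The labels give 4 trees per treatment, however, so by that number buds of both days came from the same trees. Lasting differences between those trees would recur at both days. Changed genes were also more abundant than tested genes (median FPKM 113 at 3 days and 59.4 at 7 days, against 10.8). Both lists also come from 1 fit with 1 estimate of the spread per gene. A gene of low spread therefore passes more readily in both. The expected counts and p allow for none of these, so they describe the lists and do not show independent repetition. Together 12 genes kept their direction, and 5, 6 and 7 did without control replicate 1, 3 or 4 of 7 days and 7, 7 and 5 without HC replicate 1, 3 or 4 of 7 days. The number was 26 under voom on the estimated reads, 4 with only the libraries compared and 4 with replicate number as a block. Prupe.4G155200, Prupe.3G144100, Prupe.2G181500 and Prupe.1G531700 were among those that kept their direction. Across genes, which are not independent replicates, the log2 fold changes of the 2 days had a Pearson correlation of 0.05 over the 16596 tested genes, 0.13 over the 5719 with a mean FPKM of 20 or more and 0.41 over the 301 genes changed at 3 days. Of the 301, 65.1% had the same sign at 7 days, and of the 74 genes changed at 7 days, 47.3% had the same sign at 3 days. The 179 genes higher at 3 days had a median log2 fold change of 2.81 at 3 days and 0.39 at 7 days, and the 122 lower ones -1.82 and -0.01. Over all tested genes the median was 0.15 at 3 days and 0.27 at 7 days. The genes were picked by their 3-day values, so part of the smaller change at 7 days comes from that choice. No share of equal sign over all tested genes is given for comparison.

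**Figure D3:**
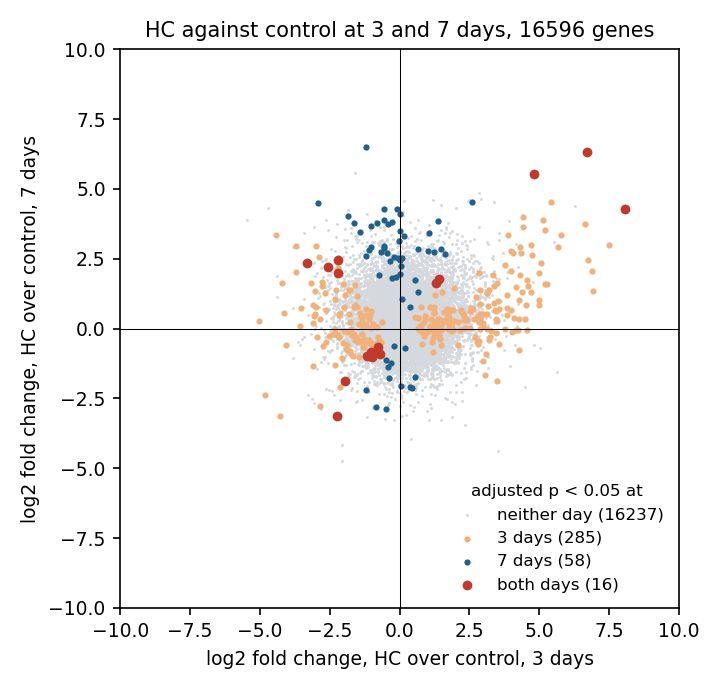
Log2 fold change of HC over control at 3 days (x axis) and at 7 days (y axis) for 16596 genes, 1 point per gene, coloured by the day at which the adjusted p was under 0.05. Of the coloured genes, 285 passed at 3 days alone, 58 at 7 days alone and 16 at both days, of which 4 lie in the upper left quadrant.

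More genes differed between the days than between HC and control. The estimated depth also differed between the days and was not separated from time. In control buds 1221 genes differed between 7 and 3 days, 566 higher and 655 lower at 7 days. Prupe.8G000400 rose from 0, 0, 0.24 and 20.7 FPKM to between 356 and 1215 FPKM (log2 fold change 8.37 ± 0.76, SE, adjusted p = 1.0e-06). Prupe.7G119300 was listed at 0 in 3 libraries and at 49.7 FPKM in replicate 3 at 3 days, and had 312 to 957 FPKM at 7 days (7.83 ± 1.22, adjusted p = 0.00054). Prupe.2G232300 had 180.5 to 7394 FPKM at 3 days and was listed at 0 in all 4 control libraries at 7 days (adjusted p = 0.0029), a call lost under voom on the estimated reads (adjusted p = 0.43, range over 20 alternatives 3.7e-05 to 0.43). Its deposited control signal at 3 days was only 28.843, for a mean of 2208.7 FPKM. Prupe.1G021600 had a signal of 3242.2 for a mean of 893.61 FPKM in the same group. The length-like factor of Prupe.2G232300 was therefore very small. Its high FPKM may stand for few reads, so the size of its fall is uncertain. Prupe.1G021600 fell from between 565 and 1392 FPKM to 0, 0, 0.22 and 15.02 FPKM (-8.65 ± 0.75, adjusted p = 4.8e-07). With median-of-ratios scaling 1167 genes differed, 673 higher and 494 lower. Fitting only the 8 control libraries gave 542 genes.

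In HC buds 1034 genes differed between 7 and 3 days, 600 higher and 434 lower at 7 days. Prupe.6G066300 rose from 0, 0, 0 and 0.38 FPKM to between 209 and 956 FPKM (8.29 ± 0.66, SE, adjusted p = 5.8e-07), and Prupe.8G155000 from 0, 0, 0 and 3.25 FPKM to between 136 and 400.2 FPKM (7.46 ± 0.81, adjusted p = 8.7e-06). Prupe.1G021500 fell from between 213 and 603 FPKM to 0, 0.95, 1.44 and 2.00 FPKM (-7.51 ± 0.66, adjusted p = 8.1e-07), and Prupe.1G021600, the next identifier, from between 129 and 544 FPKM to 0, 0.55, 0.55 and 3.08 FPKM (-7.44 ± 0.75, adjusted p = 4.1e-06). Of the DAM list, Prupe.1G531100 rose with time in HC buds (2.00 ± 0.37, adjusted p = 0.0018), and the other 3 members did not pass over all genes. Prupe.1G531400 was called over all genes in 4 of 20 alternatives (range of adjusted p 0.0047 to 0.28) and Prupe.1G531600 in 3 of 20 (0.027 to 0.34, and 0.044 without HC replicate 2 of 7 days), both among them under voom on the estimated reads and without the 2 shallowest libraries. Adjusted over the list alone, 3 of the 4 members passed in HC buds, not all in 1 direction: Prupe.1G531100 and Prupe.1G531400 (0.77, list-adjusted p = 0.019) were higher and Prupe.1G531600 (-1.80, list-adjusted p = 0.024) was lower at 7 days. In control buds 1 of the 4 passed over the list, Prupe.1G531100 (1.03, list-adjusted p = 0.044). Over all genes, control buds gained a call of Prupe.1G531100 without replicate 2 of 7 days (adjusted p = 0.021, range over 20 alternatives 0.021 to 0.25) and of Prupe.1G531600 under voom (-1.28, adjusted p = 0.042, range 0.042 to 1.00). The HC count rose to 1730 when only the 8 HC libraries were fitted, to 1979 without the 2 shallowest libraries, and to 2902 and 2977 when libraries were weighted by quality.

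The authors' deposited table for 3 days lists 1731 of 19636 genes with an adjusted p under 0.05, 841 higher and 890 lower in HC. The authors' deposited table for 7 days lists 1623 of 19439 genes, 920 higher and 703 lower. All 1677 of the authors' 3-day genes that were tested here had the same sign here (100%, Wilson 95% interval 99.8% to 100%), as did 1560 of 1567 at 7 days (99.6%, 99.1% to 99.8%). Of the genes called here, 262 of 301 at 3 days and 60 of 74 at 7 days were in the authors' deposited table with an adjusted p under 0.05 and the same sign. Both analyses use the same libraries, so this compares methods and not samples. The genes are not independent and were picked by a test on those libraries, so the intervals only describe the lists. For the DAM list at 3 days, the authors' deposited table gives log2 fold changes of -1.60 (Prupe.1G531100), -1.36 (Prupe.1G531400), -0.57 (Prupe.1G531600) and -0.65 (Prupe.1G531700), with adjusted p of 3.9e-13, 1.9e-05, 0.63 and 3.2e-06. At 7 days the authors' deposited table gives -1.01 (Prupe.1G531100), -1.14 (Prupe.1G531400), -1.54 (Prupe.1G531600) and -1.005 (Prupe.1G531700), with adjusted p of 0.012, 0.12 and 0.42 for the first 3 and a listed value of 0 for Prupe.1G531700.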

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

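The depth tests were chosen after the low numbers of genes were seen and before the tests were run. Single libraries far from the other 3 of their group were looked for in 108 groups of 4 values (library measures and named genes), and 18 stood apart. A gap of 1.00 of the range below arises by construction, since the other 3 libraries were listed at 0, and many named genes were at or near 0 in a group, so no number expected by chance is given.

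HC effects that differed between the days make up the first set of such results, 81 genes in all. Among named genes the difference (log2 fold change at 7 minus 3 days) was 9.03 for Prupe.6G021100, 7.75 for Prupe.6G021700, -5.55 for Prupe.8G110900, -5.38 for Prupe.8G000400 and 5.30 for Prupe.1G251600, with adjusted p between 0.0042 and 0.041. Prupe.1G251600 differed because it fell by 5.03 at 3 days and had a log2 fold change of 0.27 at 7 days, when it was at or near 0 in both treatments.

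Control replicate 2 at 3 days stood apart in its median rank correlation with the other 15 libraries, at 0.68 against 0.84 to 0.85 in the rest of its group (a gap of 0.912 of the group's range). It also stood apart in 3 named genes, Prupe.4G155200 (gap 1.00 of the range), Prupe.2G242800 (0.834) and Prupe.6G021100 (0.972). Among its group, replicate 3 stood apart in Prupe.8G000400 (0.93) and Prupe.7G119300 (1.00). Of the HC libraries at 3 days, replicate 1 stood apart in Prupe.2G240300 (0.901) and Prupe.6G066300 (1.00), replicate 2 in Prupe.2G232300 (0.93) and replicate 3 in Prupe.8G155000 (1.00). Of the control libraries at 7 days, replicate 1 stood apart in Prupe.I000300 (0.84), replicate 2 in Prupe.1G021600 (0.928), replicate 3 in Prupe.1G251600 (1.00) and replicate 4 in Prupe.2G242800 (1.00). Of the HC libraries at 7 days, replicate 1 stood apart in estimated depth (16.7 M reads against 2.61 to 3.58 M; 0.932), in Prupe.8G110900 (0.97) and in Prupe.1G251600 (1.00), and replicate 3 in Prupe.2G232300 (1.00).

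Few genes were above 0 in control replicate 2 at 3 days and control replicate 1 at 7 days. When the reads of the other 14 libraries were thinned to the depth of control replicate 2 (1.44 M reads), they kept between 12713 and 17124 genes with a read, against 8629 in that library. Thinned to the depth of control replicate 1 at 7 days (0.556 M reads), they kept between 12290 and 16100 genes, against 10296. This argues against fewer reads alone as the source of the low numbers. A smaller number of distinct RNA molecules behind the reads, or poorer RNA, may be the source, and neither was tested.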

How the results depend on the processing

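Which calls depended on the processing is given here for the 5 counts of changed genes, the overlap of the days and the sign shared with the authors' deposited tables. Pseudocounts, the floor of 5 FPKM, quality weights on log2 FPKM and the fit without the 2 shallowest libraries were chosen after seeing the data. The cause of each change was not tested, except that stricter thresholds lower counts by construction. At 3 days (301 genes) the count was 852 under voom, 869 under quality weights and 137 at adjusted p under 0.01, and 169 to 294 without 1 library. At 7 days (74 genes) it was 14 with only the libraries compared, 6 at adjusted p under 0.01, 44 and 120 with pseudocounts of 0.1 and 5, and 26 to 166 without 1 library. For the difference (81 genes) it was 204 under voom, 227 under quality weights, 16 at adjusted p under 0.01, 41 and 125 with pseudocounts of 0.1 and 5, and 34 to 107 without 1 library. For time in control buds (1221 genes) it was 542 with only the libraries compared and 549 at adjusted p under 0.01, and in HC buds (1034 genes) 2902 under voom, 2977 under quality weights, 1730 with only the libraries compared, 543 at adjusted p under 0.01 and 1979 without the 2 shallowest libraries. The 12 genes changed in the same direction at both days became 26 under voom, 4 with only the libraries compared, 2 at adjusted p under 0.01, 7 with a log2 change beyond 1 and 6 with a pseudocount of 0.1. Leaving out 1 library gave 5 to 18 genes. The share of the authors' genes with the same sign moved to 99.7% at 3 days with a pseudocount of 0.1 and ranged from 98.99% to 100% without 1 library. At 7 days it moved to 98.66% under voom, 98.21% and 99.87% with pseudocounts of 0.1 and 5 and 99.81% without the 2 shallowest libraries, and ranged from 96.87% to 99.81% without 1 library. Of 855 alternative values for 40 named-gene results, 750 kept their side of the threshold, 92 lost a call, 10 gained one and 3 changed sign. The 3 were Prupe.1G531600, not called in these fits, at 3 days (0.059 without control replicate 1, 0.005 without HC replicate 1, -1.06 at the other end without control replicate 2) and over time in control buds (0.017 without control replicate 1 of 3 days, -1.10 without control replicate 2).

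Replicate numbers were not treated as pairs. Correlations of deviations from the group means between equal numbers lay between -0.05 and 0.044, except 0.125 for HC replicate 1 at 3 and 7 days. At 3 days every such correlation (0.015 to 0.044) was the highest for its number, so pairing at that day is not excluded. With replicate number within day as a block the counts were 199 (3 days) and 12 (7 days), and 4 genes overlapped. With treatment and replicate number as a block they were 38 (difference), 1011 (time, control) and 809 (time, HC). The median log2 fold change over all genes was 0.15 at 3 days and 0.27 at 7 days, and -0.04 and 0.15 without the 2 shallowest libraries. The planned count tests, a filter on CPM and the alternatives for gene set tests were not run, since the matrix holds FPKM and the product-name lists were not matched.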

Other observations

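The tests by sample splits, by neighbouring identifiers, of library measures and of the genes shared over time were chosen after the counts of genes had been seen. The tests on depth, effect size and the direction of the HC effect followed a pattern already seen, but were written before they were run.

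Control and HC trees, which share no library, changed many of the same genes between 3 and 7 days. Of 566 genes that rose in control and 600 that rose in HC buds, 217 were shared (20.5 expected for independent lists; Fisher's exact test, two-sided, p = 6.6e-174). Of 655 and 434 that fell, 216 were shared (17.1 expected, Fisher's exact test, p = 4.1e-194), and 6 genes changed in opposite directions. The expected counts do not allow for the higher abundance of changed genes (median FPKM 81.1 in control and 79.8 in HC buds, against 10.8 over tested genes), so they are a description. Of the genes changed in control buds, 90.3% had the same sign in HC buds. Prupe.6G066300, named above for its rise in HC buds, went from 0, 0.43, 4.38 and 8.33 FPKM to between 197 and 603 FPKM in control buds as well. Buds of both treatments were collected on the same days after spraying, so bud development and weather between the days are not separated. Estimated depth also differed between the days in both treatments. The group medians were 7.29 M (control) and 10.8 M (HC) reads at 3 days, and 2.83 M and 3.47 M at 7 days. Thinning was not run for the time comparisons, so a library difference shared by all libraries of a day is not separated either.

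The 4 genes changed at both days in opposite directions, chosen after their values were seen, were Prupe.1G265600, Prupe.1G276700, Prupe.2G232200 and Prupe.5G164100. All 4 were lower in HC buds at 3 days and higher at 7 days. For Prupe.2G232200 the means were 761 FPKM in control and 90.9 FPKM in HC buds at 3 days, and 294 and 1248 FPKM at 7 days. Of the 81 genes whose HC effect differed between the days, 55 had a negative fold change at 3 days and a positive one at 7 days, and 13 the reverse. Genes picked for a difference tend to have opposite signs, so these 2 counts describe the list and do not test it.

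For HC at each day and time in each treatment, the real division of the libraries gave more genes than every other. That is the strongest result that 35 splits allow, and no correction was made over the counts tested. By the 4 trees per treatment in the labels, buds of both days came from the same trees, so the libraries in the time splits do not exchange freely. Chance division is therefore made less likely and not excluded. For HC against control at 3 days, 1 of 35 splits of the 8 libraries gave as many genes, the real one with 301, and the highest other gave 3. At 7 days it was 1 of 35, with 74 genes and 6 in the highest other. For time it was 1 of 35 in control (1221 against 14) and 1 of 35 in HC buds (1034 against 4). For the difference between the days, 2 of 100 drawn splits gave as many, the real one with 81 genes and another with 142. The split with 142 genes switched 0 of 4 libraries at 3 days and 3 of 4 at 7 days, so it kept the 3-day HC effect in full. Splits that exchange part of the libraries of each treatment at both days weaken the HC effect itself. The draws therefore do not test whether an equal effect at both days could give 81 genes.

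Fewer genes passed the threshold at 7 than at 3 days (74 against 301), and the estimated depth was lower at 7 days. The gap was narrower without the adjustment, with 1770 and 1906 genes at an unadjusted p under 0.05 (limma). It was also narrower in the authors' deposited tables, with 1623 and 1731 genes. Without 1 library the counts here were 26 to 166 at 7 days and 169 to 294 at 3 days. Thinning the 3-day libraries to the 7-day depths in 20 draws gave a median of 287 genes (271 to 298). Among the genes with estimated reads, the count was 289 before thinning and 71 at 7 days. The thinned counts argue against read depth as the cause, as far as the estimated depths hold. Those were less certain for HC replicates 1 and 3 and control replicate 4, the deepest libraries of 3 days. The covariance across genes between fold changes from 2 libraries per group and those from the other 2, an estimate of the size of the HC effect, was 0.178 to 0.254 at 7 days and 0.376 to 0.437 at 3 days over 18 assignments, with a ratio of the means of 0.534, while the error variance was 0.61 and 0.58. A smaller HC effect at 7 days is therefore a candidate explanation, as a hypothesis. The number of distinct molecules per library, which thinning does not lower, and differences shared by the 4 trees of a treatment remain open.

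One hypothesis was that HC moves buds along the change that control buds make from 3 to 7 days. Control libraries were divided so that the HC effect and the time change used different ones, over 5719 genes with a mean FPKM of 20 or more. At 3 days the covariance was 0.146, exceeded or equalled by 10% of the 70 divisions of the day's 8 libraries (exact permutation test, one-sided p = 0.10), which leaves the question open. At 7 days it was -0.174, the lowest of the 70 divisions (exact permutation, one-sided p = 0.0143 for values this low), which goes against the hypothesis for that day. A deviation shared by the 4 control libraries of 7 days would give a negative covariance too, so the sign may reflect those trees and not a delay. In the same way, a deviation shared by the 4 control libraries of 3 days would raise the 3-day covariance.

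Neighbouring genes, taken as consecutive identifiers among 11280 such pairs tested, changed in the same direction more often than in random placements in 3 of 4 comparisons. At 3 days 7 pairs changed together (random median 2, 10000 placements, permutation p = 0.0034, one-sided), and at 7 days 0 pairs did (random median 0). From 3 to 7 days 71 pairs changed together in control buds and 52 in HC buds (random medians 30 and 22, permutation p = 0.0001 for both, the smallest the placements can give). The placements do not allow for the higher abundance of changed genes (median FPKM 113 at 3 days, 81.1 and 79.8 over time in control and HC buds, against 10.8). Reads shared between close copies, as in the DAM list, were not separated either. These counts are therefore a description.

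The 10 most abundant genes of a library took a smaller share of its FPKM in HC than in control buds, with no overlap at either day. The share was 11.7% ± 1.69 in HC and 13.9% ± 0.361 in control buds at 3 days, and 10.7% ± 0.879 and 14.2% ± 1.21 at 7 days (SD, n = 4; exact permutation test, two-sided, p = 0.029 at each day, the smallest 4 against 4 libraries allow). Adjusted over 6 tests of library measures the p was 0.086, so neither passed the correction. Detected genes and estimated depth did not differ detectably between treatments at either day (exact permutation p from 0.26 to 0.51).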
